A study of Mus musculus with 4 samples.

How the data were processed

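Small RNA was sequenced from cultured synovial fibroblasts, the lining cells of the joint, of 8-week-old mice. Per the labels' protocols, cells were released from hind joints by enzymatic digestion, cultured for 4 passages and lysed, and RNA fractions of 20 to 30 and 70 to 100 nucleotides were cut from a gel and ligated to adaptors. The TghuTNF mouse carries a human TNF transgene and develops arthritis, and its wild-type (WT) littermates served as controls. There were 2 biological replicates of each genotype per the series design, so p-values measure the spread between these cultures. The mice had a mixed CBA and C57BL background per the labels.

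The deposited files hold 1 table per library, made by the authors with mimap version 3d per the file headers. Reads of 37 bases were matched to 707 mouse mature miRNAs with at most 2 mismatches and a hash length of 9, per the file headers. The deposited values are raw counts of matching reads per miRNA, not normalised, and the authors list beside each count its 3 parts with 0, 1 and 2 mismatches. The miRBase release, the adaptor trimming, a genome build and the rule for reads that fit several miRNAs are not given in the sources used here. The counts show that 1 read can be counted for more than 1 miRNA: the perfect matches of miR-135b equal the 1-mismatch matches of miR-135a in both WT libraries. Total matches can therefore exceed the number of reads, and of 399 names with at least 100 matches, 39 had under 5% perfect matches. Changes of near-identical miRNAs are uncertain for this reason.

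Total matches were 16680860 and 26542371 in the WT libraries and 27362819 and 22959408 in the TghuTNF libraries. A count of 0 allows up to 3 counts, which is 0.110 to 0.180 CPM (counts per 1000000 matches) depending on the library. Reads carry no molecular identifiers, so intervals and floors cover counting error only. Between 0.0112% and 0.0149% of matches per library were in no mismatch class. The files listed 590 miRNAs in any library and 497 in all 4.

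Counts were filtered with filterByExpr, which kept 442 miRNAs, and scaled with TMM. Genotypes were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 on all 4 libraries with genotype as the only term, two-sided, with Benjamini-Hochberg adjustment over the 442 miRNAs and a threshold of 0.05. CPM are TMM-scaled, errors of CPM are SD with n = 2, and errors of log2 fold changes are standard errors (SE). Of 20 miRNA lists fixed before the data were examined, 19 had at least 3 measured members. They were tested with camera of limma 3.58.1 on log2 CPM with a preset correlation of 0.01, adjusted over the 19 lists, and again with an estimated correlation and with fry. Each list's members were also adjusted over the list alone. For 71 hairpins with both arms past the filter, the log2 ratio of the arms (pseudocount 0.5) was compared with limma.

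The miRNAs named were chosen by a rule fixed before the data were examined. It takes the miRNAs known to be reported by the study, the 12 largest called changes in each direction with no overlap between genotypes, the 8 most abundant miRNAs, up to 4 members of each list (called ones by smallest p, then the most abundant) and the most abundant member of each cell type list. Members named outside this rule were chosen after their values were seen, and this is said where they appear.

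The tests were checked on simulated counts drawn from the real means and library sizes. Over 10 simulated sets of the TghuTNF against WT comparison with 200 changed miRNAs among about 441 tested, edgeR recovered 73.3% of 2-fold and 99.1% of 4-fold changes. False calls made up 1.92% of calls and 0 calls had the wrong sign. All simulated miRNAs shared 1 dispersion, and a larger share of them was changed than was called in the real data (13.3%). The real share of false calls can therefore be higher. camera called the shifted list in 10 of 10 sets with the preset correlation and in 8 with an estimated one, and fry called it in 10. None of the 3 called an unchanged list. The shifted list held up to 50 miRNAs that all rose 2-fold, and a call was an unadjusted p under 0.05. The real lists that were called were smaller or shifted less, and were adjusted over 19 lists. The check therefore does not give the power for them. The simulated miRNAs varied independently, whereas the real lists of the Dlk1-Dio3 and Hox clusters had estimated correlations of 0.40 and 0.79. The check therefore cannot show how often the preset correlation calls such lists falsely. Arm ratio changes were recovered with a slope of 1.01 on the true changes. The test of the odds of a perfect match recovered 98.8% of 50 changes of 2 on the log2 scale among 267 miRNAs, with 4.55% false calls.

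Alternatives fixed before the data were examined were DESeq2 1.42.0 (size factors and Wald test), library size only, upper quartile factors, no filter, a mean CPM of at least 100, leaving out each library, a replicate block, limma-voom, the likelihood ratio and robust tests of edgeR, summing by stem, other thresholds, removal of the 5 most abundant miRNAs, and at least 50 reads on both arms. Leaving out a library leaves n = 1 in its genotype, so p-values then rest on the spread of the other genotype. Counting perfect matches only, or matches with 0 or 1 mismatch, was added after the shared reads were seen. Hairpin positions come from a name match to RefSeq genes on GRCm38, with host genes from GENCODE, and 420 of the 442 names matched. Parsing, exact binomial intervals and figures used Python 3.11.15, scipy 1.17.1 and matplotlib 3.10.9.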

Results

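Mature miRNAs were counted in 4 small RNA libraries of mouse synovial fibroblasts, 2 from WT mice and 2 from TghuTNF littermates, to find miRNAs that differ between arthritic and healthy fibroblasts. Total matches per library were 16680860 and 26542371 for WT and 27362819 and 22959408 for TghuTNF. The libraries listed 532, 541, 556 and 545 miRNAs. Replicate libraries correlated across miRNAs with r = 0.995 (WT) and 0.990 (TghuTNF) on the log2 CPM scale, against 0.969 to 0.980 between genotypes. Neither pair of replicates held the same counts within sampling noise (chi-square per degree of freedom of 532 and 553), so neither pair was a duplicated library, and the libraries are biological replicates per the series design.

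miR-21 was the most abundant miRNA in every library and took 15.79% of matches in WT replicate 1 (exact 95% binomial interval 15.77% to 15.81%) and 18.72% in TghuTNF replicate 2 (18.70% to 18.73%), the lowest and highest of the 4 libraries. The 8 most abundant miRNAs together took 66.6% to 68.3%. miR-21 stood at 170381 ± 14260.0 CPM in WT and 185228 ± 7858 in TghuTNF (SD, n = 2), a log2 fold change of 0.12 ± 0.14 (SE). let-7c (0.07 ± 0.14), miR-143 (-0.11 ± 0.14), let-7b (-0.018 ± 0.14), let-7a (-0.040 ± 0.16), let-7f (-0.049 ± 0.16), miR-125b-5p (0.31 ± 0.15) and miR-34c (-0.026 ± 0.15) likewise did not pass the test. let-7a and let-7f differ by few bases and share reads in these counts.

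miR-146a, which NF-kB signalling induces and which represses Irak1 and Traf6, rose 6.22-fold in TghuTNF fibroblasts, from 1479.7 ± 42.7 to 9207 ± 3755 CPM (SD, n = 2; edgeR adjusted p = 7.8e-05). miR-155, another inflammatory miRNA, rose 2.64-fold from 148 ± 22.7 to 391 ± 80.6 CPM (edgeR adjusted p = 0.0019), and miR-31 rose 2.63-fold from 57.5 ± 7.08 to 151 ± 25.6 CPM (edgeR adjusted p = 0.0021). miR-146b, which shares its seed with miR-146a but is made from another locus, went the other way and was 3.47-fold lower, at 19010.1 ± 7589 CPM in WT and 5484 ± 378 in TghuTNF (edgeR adjusted p = 0.00081). Of 16 measured miRNAs known as induced by TNF, NF-kB or Toll-like receptor signalling, 4 rose (miR-146a, miR-155, miR-31 and miR-223), 3 fell and 9 did not pass, with the same counts when adjusted over the list alone. As a group they did not pass (camera adjusted p = 0.73). In GRCm38, Mir146 lies on chromosome 11 at 43374397 to 43374461 outside annotated genes, Mir155 on chromosome 16 at 84714140 to 84714204 in an exon of Mir155hg, and Mir146b on chromosome 19 at 46342762 to 46342870 in an intron of Mfsd13a.

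**Figure D1:**
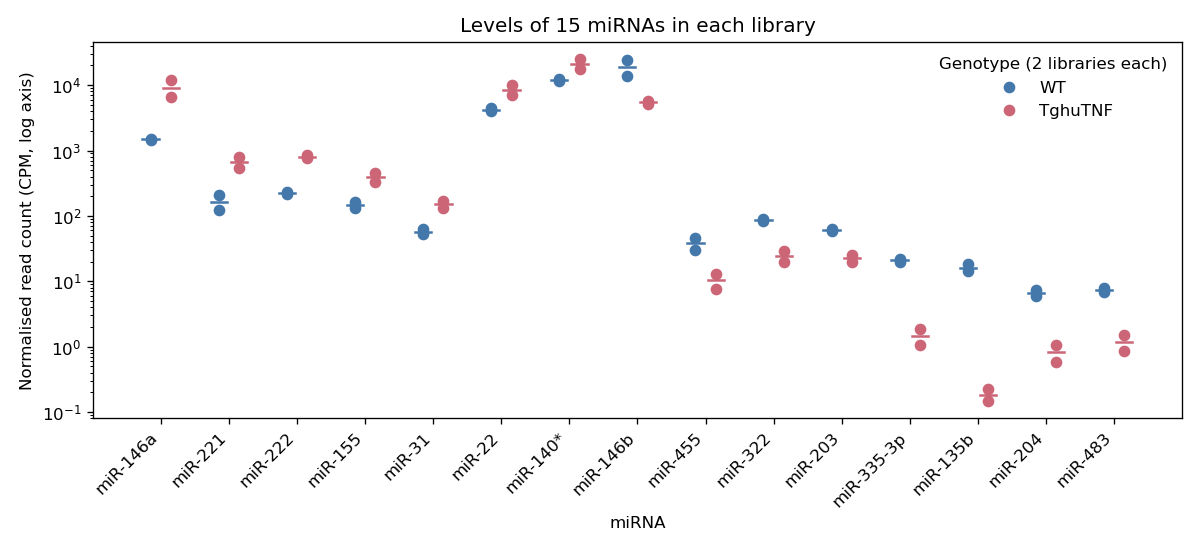
Normalised read counts (CPM, log axis) of 15 miRNAs in each library, with points for single libraries and bars for the mean of 2 libraries per genotype. Both TghuTNF points of miR-146a lie above both WT points, and both TghuTNF points of miR-146b lie below them.

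miR-221 and miR-222, an X-linked pair that targets the cell cycle inhibitor p27, both rose. miR-222 went from 226 ± 13.5 to 809 ± 58.3 CPM, a 3.58-fold change (SD, n = 2; edgeR adjusted p = 0.00011), and miR-221 from 165 ± 58.1 to 671 ± 172 CPM, a 4.07-fold change (edgeR adjusted p = 0.00082). miR-323-3p stood at 1.89 ± 0.18 CPM in WT and 2.89 ± 0.065 in TghuTNF and did not pass (log2 fold change 0.60 ± 0.33, edgeR adjusted p = 0.25). These 3 miRNAs are known to have been reported by the study from these samples, so their direction is not independent evidence. Of the 3, 2 rose over all miRNAs and 2 when adjusted over the list alone; the list passed camera (adjusted p = 0.0080) but had an adjusted p = 0.82 with an estimated correlation. Mir221 and Mir222 lie on chromosome X at 19146294 to 19146388 and 19146893 to 19146971, outside annotated genes.

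Over all 442 tested miRNAs, 59 passed at an adjusted p of 0.05 with edgeR, 21 of them higher and 38 lower in TghuTNF, and 128 had an unadjusted p under 0.05. All 59 had both TghuTNF libraries on the same side of both WT libraries, as did 60.6% of all tested miRNAs. For a single miRNA chance alone gives 33.3%. All miRNAs come from the same libraries and some share reads, so setting these shares side by side is not a test. Changes of at least 2-fold were found for 19 higher and 31 lower miRNAs. Besides miR-146a, miR-221 and miR-222, the 12 largest rises included miR-329 (9.42-fold, 0.73 ± 0.092 to 6.84 ± 4.65 CPM), miR-375 (8.21-fold, 0.21 to 1.75 CPM), miR-223 (6.60-fold, 0.45 to 2.83 CPM), miR-495 (5.60-fold, 0.67 to 3.76 CPM), miR-615-3p (4.35-fold, 5.35 to 23.1 CPM), miR-122 (3.85-fold, 2.47 to 9.55 CPM) and miR-215 (3.78-fold, 5.13 to 19.5 CPM). miR-582-5p and miR-592 also rose, from 0.35 to 1.27 and from 0.66 to 1.92 CPM, the latter uncertain because only 1.63% of its matches were perfect. Without TghuTNF replicate 2, miR-329 rose 4.82-fold and miR-615-3p 2.68-fold, and without TghuTNF replicate 1, 61 miRNAs were higher and 92 lower. Calls by edgeR ended for miR-375 (adjusted p = 0.058) and miR-223 (0.051) without WT replicate 2, for miR-582-5p (0.11 to 0.32) without WT replicate 1, WT replicate 2 or TghuTNF replicate 2, and for miR-592 (0.22 and 0.40) without WT replicate 1 or WT replicate 2.

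miR-135b fell 87.0-fold, from 16.2 ± 2.94 to 0.18 ± 0.055 CPM (SD, n = 2; edgeR adjusted p = 2.6e-06), where the TghuTNF libraries held 4 and 5 reads. With perfect matches these were 1 and 3 reads, the ratio of WT to TghuTNF reads per perfect match was 179 (exact 95% interval 69.7 to 659.8, counting error only), and the fitted log2 fold change was -7.43. The larger fitted fall of miR-135a, 93.6-fold, is uncertain, since only 1.66% of its matches were perfect and its counts largely repeat the reads of miR-135b. Both arms of mir-335, which lies in an intron of the imprinted gene Mest, fell: miR-335-5p 19.4-fold from 25.1 ± 15.3 CPM and miR-335-3p 14.1-fold from 20.7 ± 1.88 CPM. miR-204 fell 8.05-fold, miR-483, in an intron of Igf2, 6.12-fold, and miR-3475 4.14-fold. The star strand of mir-146b, miR-146b*, fell 4.03-fold, in the same direction as its partner. Without TghuTNF replicate 1 the falls were 36.5-fold for miR-335-5p, 12.1-fold for miR-204 and 10.5-fold for miR-3475. Without WT replicate 1, miR-335-5p fell 11.2-fold and miR-3475 lost its call (edgeR adjusted p = 0.087), and without TghuTNF replicate 2, miR-3475 fell 2.76-fold. Mir135b lies on chromosome 1 at 132198088 to 132198184 in an intron of Lemd1, Mir335 on chromosome 6 at 30741299 to 30741396, Mir204 on chromosome 19 at 22750605 to 22750672 in an intron of Trpm3, and Mir483 on chromosome 7 at 142654924 to 142654996.

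miRNAs of the X-linked cluster of miR-322 and miR-503, which restrains the cell cycle, were lower in TghuTNF. The list of this cluster and the miR-15/16 family had 17 measured members, of which 8 fell, 0 rose and 9 did not pass. All 8 belong to the 10 measured members of the cluster. When adjusted over the list alone 12 fell, the 10 cluster members and miR-15b (-0.84) and miR-195 (-0.67), named after their values were seen; the 7 members outside the cluster had a median of -0.40. miR-322 went from 86.3 ± 6.06 to 24.4 ± 7.0 CPM (log2 fold change -1.82 ± 0.26), miR-503 changed by -2.30 ± 0.35, miR-503* by -2.04 ± 0.32, miR-322* by -2.44 ± 0.45, miR-542-5p by -2.09 ± 0.38 and miR-542-3p by -1.51 ± 0.26. The median log2 fold change of the list was -1.51 (camera adjusted p = 2.4e-07; adjusted p = 0.25 with an estimated correlation). Keeping only miRNAs with a mean CPM of at least 100 removes every measured member of the cluster. The rest of the list then had a median of -0.51 and was not called (camera adjusted p = 0.40), which does not test the cluster. Without TghuTNF replicate 1, miR-322* changed by -3.60. Mir322 lies on chromosome X at 53054255 to 53054349.

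Of 39 measured miRNAs in the list for the large cluster in introns of Sfmbt2, a mouse imprinted gene on chromosome 2, 9 fell, 0 rose and 30 did not pass, and 13 fell when adjusted over the list alone. The list passed camera with the preset correlation (median log2 fold change -0.67, adjusted p = 1.8e-09) but had an adjusted p = 0.25 with an estimated correlation. The list takes whole miRNA families: of its members, 30 have a hairpin in Sfmbt2, 7 map elsewhere and 2 had no matched hairpin. miR-669c went from 739 ± 79.9 to 459 ± 30.5 CPM (log2 fold change -0.69 ± 0.18, edgeR adjusted p = 0.034) and miR-467e changed by -0.99 ± 0.27. Of the 30 with a hairpin in Sfmbt2, 7 fell, and their median was -0.66. The 7 that map elsewhere had a median of -0.69, with 2 of them called lower, so the fall was not limited to that locus. Of the 9 that fell, 4 had under 5% perfect matches and are uncertain: miR-467h (-1.06 ± 0.28, 0%), miR-669n (-0.69 ± 0.18, 0.12%), and miR-466f-5p (0.48%) and miR-467d (2.78%), the last pair named after their values were seen. miR-669n stood at 0.27 with perfect matches only, and neither it nor miR-467h has a hairpin in Sfmbt2. Calls ended for miR-467e and miR-467h without WT replicate 1 or WT replicate 2, and for miR-669c without WT replicate 2 or TghuTNF replicate 2 (edgeR adjusted p 0.056 to 0.28), and with perfect matches 3 of 27 tested members fell.

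Of 63 measured miRNAs of the imprinted Dlk1-Dio3 cluster on chromosome 12, 2 rose (miR-329 and miR-495), 0 fell and 61 did not pass, with 2 again when adjusted over the list alone, and 60 had a positive log2 fold change. The list passed camera with the preset correlation (median 0.55, adjusted p = 1.8e-09) but had an adjusted p = 0.83 with an estimated correlation. The abundant members miR-379 (2130.3 ± 5.29 against 3207 ± 943 CPM, 0.59 ± 0.20) and miR-127 (863 ± 107 against 1369 ± 371 CPM, 0.67 ± 0.21) did not pass. Their log2 fold changes were 0.79 (miR-379) and 0.84 (miR-127) without TghuTNF replicate 1, against 0.23 and 0.33 without TghuTNF replicate 2. That of miR-127 was 0.79 without WT replicate 2. Each of these fits left 1 library in a genotype. The list's median log2 CPM lay 0.26 above the WT mean in TghuTNF replicate 1 and 0.76 above it in TghuTNF replicate 2, a library that also had 11.67% of matches with 2 mismatches against 8.21% to 8.73% in the others. Without TghuTNF replicate 2 the list's median log2 fold change was 0.23 (camera adjusted p = 0.0018), and with perfect matches only it was 0.46.

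The miRNAs within Hox clusters passed the list test with 8 members (median 0.40, camera adjusted p = 0.031; adjusted p = 0.83 with an estimated correlation), and 1 of them, miR-615-3p, rose, also when adjusted over the list alone. miR-196b (0.23 ± 0.17), miR-196a (0.23 ± 0.17) and miR-10b (0.40 ± 0.19) did not pass. In WT replicate 1, miR-196a and miR-196b had 58909 and 59330 matches, and miR-10a and miR-10b 13309 and 13938. Within each pair the counts were also close in the other libraries, so the members are not separate measurements. Only 7.42% of the matches of miR-10b were perfect, and miR-10a was named after its values were seen. This list's call ended without the filter (adjusted p = 0.14), with a mean CPM of at least 100 (0.33), without WT replicate 2 (0.17; median 0.27) and without TghuTNF replicate 2 (0.19; median 0.23), the library with the most 2-mismatch matches. The median was 0.52 without WT replicate 1 and 0.55 without TghuTNF replicate 1. With perfect matches only the list kept its call (median 0.86, camera adjusted p = 0.027). The sign of miR-196b then turned to -0.15, while miR-196a was called at 1.03.

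**Figure D2:**
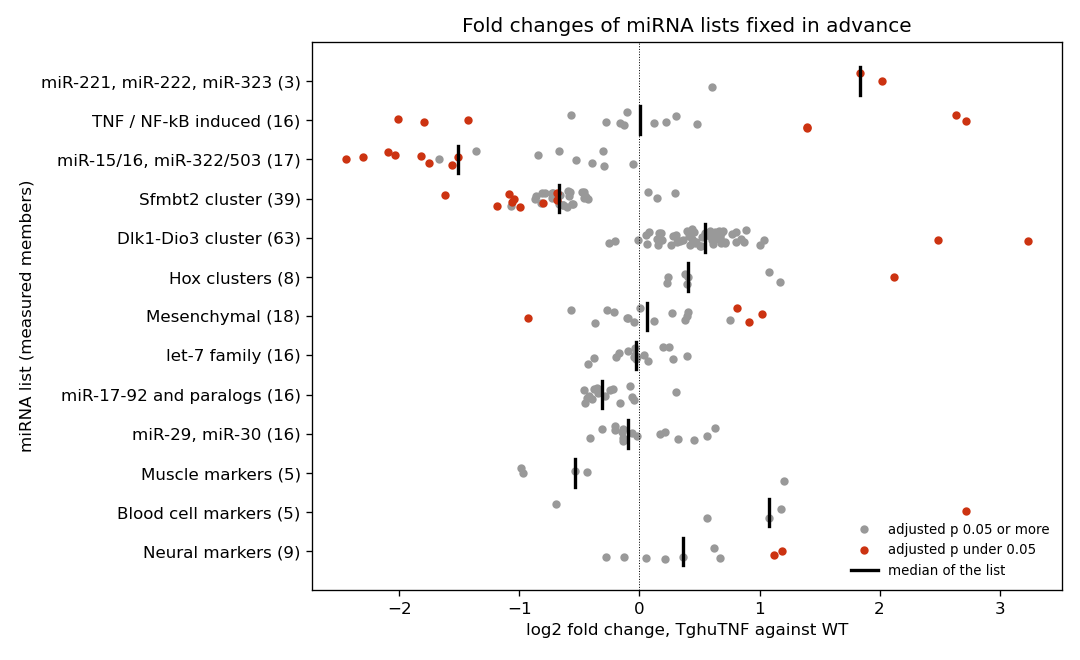
log2 fold change (TghuTNF against WT) of each measured member of 13 miRNA lists, with red points for an adjusted p under 0.05 and black bars for list medians. The miR-15/16 list with the miR-322 and miR-503 cluster has the lowest median of these lists, -1.51, and the let-7 list sits at -0.033.

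Other groups did not pass as lists. Of 18 mesenchymal miRNAs, 3 rose, miR-22 (2.03-fold, 4226 ± 315 to 8569 ± 2133 CPM), miR-140* (1.75-fold, 12085 ± 542.1 to 21189.7 ± 4969 CPM) and miR-140 (1.88-fold), 1 fell, miR-214 (1.90-fold), and 14 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 0.62). Without TghuTNF replicate 2, miR-140 and miR-140* lost their calls (edgeR adjusted p = 0.14 and 0.10), and miR-214 lost its call without WT replicate 1 (0.45) and with a mean CPM of at least 100 (0.0999). Of 19 miRNAs reported elsewhere in rheumatoid arthritis, 3 rose (miR-146a, miR-155 and miR-223), 1 fell (miR-203, 2.69-fold) and 15 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 0.88).

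No member of 6 further lists passed edgeR's test, over all miRNAs or when adjusted over the list alone. These were the let-7 family (16 members, camera adjusted p = 0.91), the miR-17-92 cluster and its paralogs (16 members, median -0.32, 0.11), miR-29 and miR-30 (16 members, 0.91), miR-23/27/24 (9 members, 0.88), miR-99/100 and miR-125 (9 members, 0.88) and the p53-induced miR-34 family (5 members, 0.66). Examples are miR-93 (-0.16 ± 0.16), miR-20a (-0.34 ± 0.20), miR-17 (-0.35 ± 0.20), miR-92a (-0.47 ± 0.20), miR-30a (-0.13 ± 0.15), miR-29a (-0.023 ± 0.16), miR-24 (-0.066 ± 0.17), miR-27b (-0.082 ± 0.16), miR-99b (0.12 ± 0.16), miR-100 (-0.046 ± 0.15) and miR-34a (0.44 ± 0.20). In WT replicate 1, miR-17 and miR-20a had 17926 and 18072 matches, and their counts were also close in the other libraries. They are therefore not separate measurements. miR-17, miR-20a and miR-92a changed by -0.69, -0.68 and -0.67 without TghuTNF replicate 1, which leaves 1 library of that genotype. The miR-17-92 median was then -0.57, against -0.19 without TghuTNF replicate 2. The medians of 3 lists (let-7, miR-29 with miR-30, and miR-99 with miR-125) were negative while camera's direction was up.

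Markers of other cell types moved in part with genotype. miR-126-3p, an endothelial miRNA, was 1.73-fold lower (103 ± 12 to 59.6 ± 2.34 CPM), and lost its call without WT replicate 1 (edgeR adjusted p = 0.30) or WT replicate 2 (0.10). Of 5 blood cell miRNAs 1 rose, miR-223, and 3 rose and 1 fell when adjusted over the list alone; miR-142-3p stood at 8.90 ± 5.32 against 18.6 ± 3.17 CPM and miR-342-3p at 53.7 ± 7.74 against 79.2 ± 11.4 CPM. Of 8 epithelial miRNAs, 1 fell, miR-203, as also when adjusted over the list alone, while miR-182 stood at 0.68 ± 0.28. Of 5 muscle miRNAs, 0 passed, and 4 fell and 1 rose when adjusted over the list alone, with miR-206 at -0.53 ± 0.18 and miR-1 at -0.43 ± 0.19. The 1 that rose was the scarce miR-499, named after its values were seen. Of 9 neural miRNAs, 2 rose, miR-129-3p (2.28-fold) and miR-138 (2.17-fold), and 3 when adjusted over the list alone, and miR-129-5p stood at 0.67 ± 0.20. All 4 chondrocyte miRNAs passed both ways, miR-140 and miR-140* higher and miR-455 (3.67-fold) and miR-455* (2.25-fold) lower. None of the 5 cell type lists with at least 3 members passed camera (adjusted p 0.11 to 0.88), though the blood cell list did without WT replicate 1, TghuTNF replicate 1 or TghuTNF replicate 2 (adjusted p = 0.0048, 0.041 and 0.040). These calls use the preset correlation; with all libraries the blood cell list had an adjusted p = 0.83 with an estimated correlation and 0.35 with fry. The log2 fold change of miR-142-3p, 1.08 with all libraries, was 1.85 without WT replicate 1 and 0.55 without WT replicate 2. In these fits, which leave 1 WT library, the blood cell median was 2.13 and 0.48, and miR-182 stood at 1.12 and 0.34. Values without TghuTNF replicate 1 were 0.82 (miR-142-3p), 0.79 (miR-182), 0.63 (miR-342-3p) and -0.75 (miR-206). Those without TghuTNF replicate 2 were 1.23 (miR-142-3p) and 0.71 (miR-129-5p), and both fits leave 1 TghuTNF library. Calls of miR-129-3p and miR-138 ended without WT replicate 1 or WT replicate 2, and that of miR-455* without WT replicate 1 (edgeR adjusted p 0.051 to 0.29).

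With perfect matches only, 380 miRNAs were tested and 50 called, 19 higher and 31 lower. Of these, 45 were among the 59 called with up to 2 mismatches, 6 of the 59 were not tested and 8 were tested and not called. miR-146a kept a log2 fold change of 2.65, miR-221 of 2.22, miR-222 of 1.79, miR-155 of 1.38, miR-322 of -1.81 and miR-335-3p of -3.97. miR-135a, miR-592, miR-582-5p and miR-467h were not tested with perfect matches, and miR-138 was not called (edgeR adjusted p = 0.071).

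**Figure D3:**
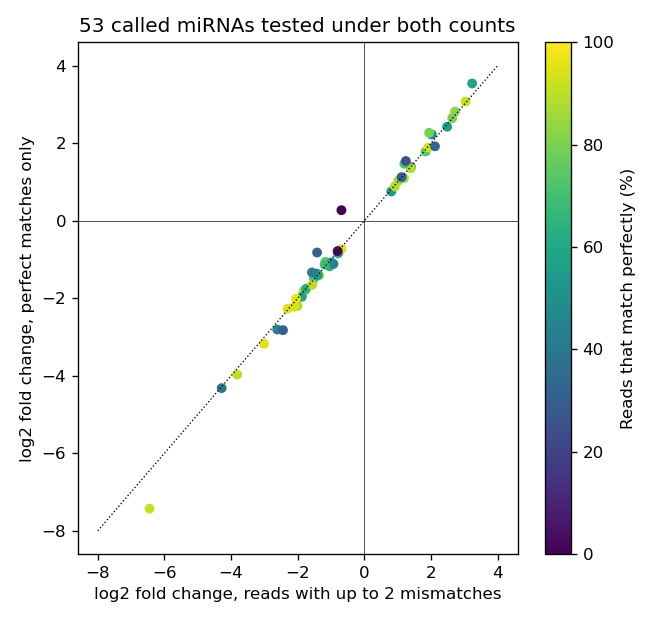
log2 fold change with up to 2 mismatches (x axis) against perfect matches only (y axis) for the 53 called miRNAs tested in both, coloured by the percentage of matches that were perfect. Of these points, 52 have the same sign on both axes, and the exception is miR-669n, at -0.69 and 0.27.

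The balance between the 2 arms of a hairpin was compared for 71 hairpins. limma called 0 of them, and 4 had an unadjusted p under 0.05: mir-30b (log2 ratio change of star to guide -0.81 ± 0.26), mir-196a (0.91 ± 0.32), mir-214 (0.88 ± 0.33) and mir-22 (-0.73 ± 0.28), named after their values were seen. With perfect matches the change of mir-196a was -0.0057 ± 0.27, while mir-30b stood at -1.08 ± 0.29, mir-214 at 1.01 ± 0.34 and mir-22 at -0.76 ± 0.31. Counting only hairpins with at least 50 reads on both arms gave 0 of 43, and perfect matches gave 0 of 59.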

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

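The share of matches with 2 mismatches, a part of the files that the comparisons do not use on its own, was looked at after the data were seen. It was 11.67% in TghuTNF replicate 2 (exact 95% binomial interval 11.66% to 11.68%, counting error only), above 8.64% and 8.73% in the WT libraries and 8.21% in TghuTNF replicate 1. Per miRNA, the odds of a perfect match were compared between genotypes for 267 miRNAs with at least 100 matches in each library; limma called 0, and 16 had an unadjusted p under 0.05.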

How the results depend on the processing

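Counting perfect matches only, and matches with 0 or 1 mismatch, were chosen after the data were seen. The other alternatives were fixed before the data were examined. The number of called miRNAs was 21 higher and 38 lower in the main analysis. It stayed within 1.5 times of that with DESeq2 size factors, library size only, upper quartile factors, DESeq2's Wald test, limma-voom, the likelihood ratio test, the robust test, summing by stem, removal of the 5 most abundant miRNAs, perfect matches and 0 or 1 mismatch. No filter gave 39 higher and 54 lower, a mean CPM of at least 100 gave 8 and 6 of only 135 tested miRNAs, an adjusted p of 0.10 gave 35 and 51, and 0.01 gave 13 and 23. Leaving out single libraries gave 17 to 61 higher and 29 to 92 lower, with the most calls without TghuTNF replicate 1; the lone library is then assumed to vary like the other genotype. Of the 59 main calls, 41 remained without WT replicate 1, 37 without WT replicate 2, 58 without TghuTNF replicate 1 and 54 without TghuTNF replicate 2. The cause of these differences was not tested. With the replicate number as a block, 34 were higher and 53 lower; libraries of the same number deviated from their genotype means with a correlation of -0.088 over only 2 pairs. What the replicate number marks is not given in the sources used here, and 2 pairs do not settle it.

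Of the 43 named miRNAs called, 27 kept direction and call in each alternative that tested them; miR-146a ranged from 2.12 to 2.93, miR-221 from 1.70 to 2.43 and miR-222 from 1.73 to 1.90. Upper quartile factors shifted the median of all miRNAs by -0.108 against TMM and ended the calls of miR-582-5p, miR-592, miR-3475, miR-140, miR-214 and miR-138. DESeq2 size factors ended that of miR-582-5p, the Wald test of DESeq2 that of miR-592, perfect matches that of miR-138, a mean CPM of at least 100 and summing by stem that of miR-214, limma-voom those of miR-582-5p and miR-214, and 0 or 1 mismatch those of miR-582-5p, miR-140, miR-214, miR-138, miR-467e, miR-126-3p and miR-669c. Named miRNAs not called in the main analysis gained 40 calls. No filter and the replicate block each called miR-379, miR-127, miR-142-3p, miR-182, miR-206 and miR-129-5p, and summing by stem the same ones but miR-182. DESeq2's Wald test and limma-voom called miR-129-5p (adjusted p = 0.014 and 0.047), the robust test miR-127 and miR-129-5p (0.046 and 0.037), and perfect matches miR-196a. Leaving out TghuTNF replicate 1 called 13, among them miR-486, miR-183, miR-133a and miR-133b, and each other library 1 or 2. The 5 lists called with the preset correlation include that of the miRNAs reported by the study from these samples, which is not independent evidence. Of the 5 lists, 0 were called with an estimated correlation, 2 with fry and 1 of 12 with a mean CPM of at least 100. The count was 4 to 6 with single libraries left out.

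Signs turned for 15 named miRNAs and 6 lists, and in the reversed setting none of them passed. The only one called in the main analysis was miR-669n, at 0.27 with perfect matches, which were 0.12% of its matches, and 0.22 with 0 or 1 mismatch. The cause of these sign changes was not tested. With perfect matches let-7a was 0.028, miR-100 0.092 and miR-196b -0.15, and the medians of the let-7, miR-23/27/24 and miR-99 to miR-125 lists were 0.028, -0.035 and 0.046. With 0 or 1 mismatch let-7b was 0.012, let-7a 0.020, let-7f 0.0044, miR-34c 0.0091, miR-29a 0.032, miR-125a-5p 0.072 and miR-34b-5p 0.15, and the let-7 and miR-99 to miR-125 medians were 0.044 and 0.072. Upper quartile factors gave let-7c -0.037 and list medians of -0.097 (inflammation), -0.10 (miR-23/27/24) and -0.053 (mesenchymal), all within that scaling's shift. Library size only gave -0.0074 (inflammation) and -0.0089 (miR-23/27/24), and no filter -0.0040 (miR-23/27/24) and -0.0083 (mesenchymal). A mean CPM of at least 100 gave let-7b 0.0053, miR-29a 0.0010 and medians of 0.058 (miR-99 to miR-125), -0.021 (mesenchymal) and -0.0017 (miR-34 family). Summing by stem gave miR-34c* -0.038. With single libraries left out, let-7b ranged from -0.14 to 0.052, let-7a from -0.18 to 0.11, let-7f from -0.19 to 0.11, miR-34c from -0.085 to 0.033, miR-29a from -0.15 to 0.067, miR-24 from -0.25 to 0.15, miR-23b from -0.28 to 0.027, miR-99b from -0.058 to 0.25, miR-125a-5p from -0.53 to 0.051, miR-100 from -0.17 to 0.043 and miR-34c* from -0.11 to 0.34. List medians then ranged from -0.16 to 0.086 (let-7), -0.085 to 0.070 (miR-23/27/24), -0.17 to 0.087 (miR-99 to miR-125), -0.022 to 0.15 (mesenchymal) and -0.083 to 0.29 (miR-34 family). Depth limits miRNAs near the floor of 0.110 to 0.180 CPM, such as miR-135b in TghuTNF.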

Other observations

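The tests of explanations in this part were chosen after the result they bear on was seen, except that of the whole X chromosome. Its median had not been seen, although single X-linked miRNAs such as miR-221, miR-222 and miR-223 had. The camera, fry and edgeR results repeated here come from tests fixed before the data were examined, apart from counts of perfect matches. Beyond the cluster of miR-322 and miR-503, 30 other X-linked miRNAs were measured, of which 3 rose (miR-221, miR-222 and miR-223) and 3 fell (miR-676, miR-676* and miR-3475). miR-676 went from 422 ± 36.6 to 201 ± 0.065 CPM (SD, n = 2; edgeR adjusted p = 0.0029). miR-676 and miR-676* were named after their values were seen.

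miR-146a, miR-155, miR-221, miR-222 and miR-31 were higher in TghuTNF, and leukocytes carried over into these cultures could raise miR-146a and miR-155. The summed rise of miR-142-3p and miR-223, both abundant in leukocytes, was small beside that of miR-146a. Against the WT mean it was at most 0.2906% of the CPM rise of miR-146a in either TghuTNF library, far below what such cells would bring. Against single WT libraries it was 0.053% to 0.370%. For miR-155 it was at most 7.941% (1.93% to 9.25% against single WT libraries), which argues against leukocytes as its whole source and leaves a smaller part open. The sum leaves out miR-142-5p, the other arm of that hairpin, named after its values were seen. It had 41 and 17 reads in WT and 116 and 55 in TghuTNF, so the percentages are somewhat too low. Also left out was miR-342-3p of the blood cell list (53.7 ± 7.74 CPM in WT and 79.2 ± 11.4 in TghuTNF), which rose by more CPM than miR-142-3p. miR-486 of that list stood lower in TghuTNF (25.7 ± 2.88 against 15.8 ± 4.75 CPM). The percentages for miR-155 thus depend on which miRNAs are summed. Per the labels, few cultured cells stained for the macrophage marker Mac1. Reads of miR-146b, whose sequence is nearly that of miR-146a, would lower miR-146a rather than raise it, since miR-146b itself changed by -1.793 on the log2 scale. An effect of the TNF transgene on the fibroblasts themselves stays a hypothesis, since it was found and tested on the same 4 libraries.

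The X-linked cluster of miR-322, miR-503, miR-351, miR-542 and miR-450 was lower in TghuTNF, with 8 of its 10 measured miRNAs called and log2 fold changes from -2.44 to -1.36. A smaller share of myogenic cells could lower it, since miR-206 and miR-1 also stood lower. The scarce miR-499, another muscle miRNA, went the other way, with 6 and 19 reads in WT and 40 and 25 in TghuTNF. It was named after its values were seen. However, the cluster's median of -1.786 lay below miR-206 by more than 2 SE of miR-206 (bound -0.89), and miR-1 had a bound of -0.82. The scarce miR-133a (-0.98 ± 0.38) and miR-133b (-0.97 ± 0.38), which are near-identical, have 2 SE bounds of -1.73 and -1.72, below 4 of the 10 cluster members, and on their own do not exclude it. Lower output of the whole X chromosome would lower its other miRNAs as well, and their median was 0.01973 with an interquartile range of -0.17 to 0.30. A change of this cluster within the fibroblasts remains a candidate explanation, as a hypothesis from these libraries.

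In 2 imprinted clusters most measured miRNAs leaned 1 way, with 60 of 63 Dlk1-Dio3 miRNAs positive (2 called higher) and 36 of 39 in the Sfmbt2 list negative (9 called lower), but camera with an estimated correlation called neither (adjusted p = 0.83 and 0.25). TghuTNF replicate 1 alone also had a raised Dlk1-Dio3 median, by 0.2579 on the log2 scale over the WT mean, beyond the 2 WT libraries (-0.022 and 0.022). The shift in TghuTNF replicate 2 was 0.76, so the TghuTNF libraries lay further apart than TghuTNF replicate 1 lay from WT. A single library therefore cannot settle whether TghuTNF replicate 2 is the whole source. TghuTNF replicate 2 had 11.67% of matches at 2 mismatches, and the list median was 0.46 with perfect matches only. A contribution from that library stays open. Of the 39 members of the Sfmbt2 list, 30 have a hairpin there (median -0.66), and the 7 that map elsewhere had a median of -0.69. The fall was thus not limited to members at that locus. With perfect matches only, the list's median was -0.6772 over the 27 members then tested, so mismatched reads shared between members are not the whole source of it. A part from shared reads stays open, since 3 rather than 9 members were then called and the remaining members were not tested. A joint fall of paternally expressed imprinted miRNAs may lie behind the Sfmbt2 change: miR-335-5p and miR-335-3p in Mest and miR-483 in Igf2 also fell, but miR-296-3p, miR-296-5p and miR-298, at another imprinted locus, had a median of -0.2361 with intervals (2 SE) that together span -1.04 to 0.57, too wide to decide. fry called the Sfmbt2 list (adjusted p = 0.044) and not the Dlk1-Dio3 list (0.35), and a chance shift of correlated members stays open.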
